A study of Homo sapiens with 18 samples.

How the data were processed

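The study sequenced RNA of H1299 cells, a human non-small cell lung cancer line without endogenous p53 protein, that carry a doxycycline-inducible wild-type p53 fused to FKBP12F36V and an HA tag. Per the labels, cells were plated 24 h before treatment and received doxycycline and then an AceTAG compound or DMSO for 24 h. The 18 libraries form 6 groups of 3, from induced and non-induced cells given DMSO, the p300/CBP compound or the PCAF/GCN5 compound. The labels give no dose and do not say whether non-induced cells received doxycycline. Sample titles name p53-FKBP12F36V for induced samples only, so they do not show the construct in non-induced ones. They also do not say whether replicates were separate cultures, so every p-value here measures the spread between these samples only. Replicate numbers follow the order of the libraries within a group.

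The authors made total RNA libraries with a directional kit and named StringTie and DESeq2 as processing tools, without versions. The aligner, genome build, annotation, counting program and the use of strand are not stated. The deposited tables, 4 in number, each compare 1 compound with DMSO in 1 state. Per the file headers, each table holds raw counts per gene for 6 libraries, which were used here as counts. Each also holds a scaled count per library and a mean over libraries, deposited as a signal normalised by DESeq2. Fold changes and their errors were deposited as log2 values, and each gene has a p-value and an adjusted p, both made by the authors with the Wald test of DESeq2, per the file headers. In the 2 deposited tables of induced cells the log2 fold change is DMSO minus compound, so its sign was turned for every comparison made here. In 1 table the deposited DMSO counts and the p columns count as other units, because the line of the gene ANK2 is broken over several lines and a line of totals follows. DMSO counts of that table were therefore taken from the other table of non-induced cells, where they are equal in every intact line, and ANK2 was left out throughout. This left 60622 genes, of which 60294 identifiers matched the table of current gene names. Gene positions in the files fell on GRCh38: of 58515 identifiers found in GENCODE release 29, 46551 (79.6%) had the same chromosome, start and end. The mean signal of the deposited tables was above 0 for 4050 of the 28399 genes with no count in any non-induced library, and for 3950 of 28032 in induced libraries. It was also above 0 for 4343 of the 24165 genes with no count in any of the 18 libraries, so the authors' DESeq2 fit drew on counts beyond those deposited for these 18.

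Total counts per library ran from 9.1 to 29.2 M. A count of 0 in a library allows a level of up to 3 counts, which is 0.103 CPM in the deepest library and 0.331 CPM in the shallowest. Such floors cover counting error only, while the 95% intervals given for differences between compounds come from the standard error of the fit. CPM are counts scaled to a library total of 1e6.

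Each comparison was fitted on its own groups with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr on the groups, glmQLFit and the quasi-likelihood F test, 2-sided. P-values were adjusted by Benjamini-Hochberg over the genes tested, and genes with an adjusted p below 0.05 were called. The standard error of a log2 fold change was taken as its size divided by the square root of F. The 7 comparisons of 2 groups were each compound with DMSO in each state, the compounds with each other in each state, and induced with non-induced cells in DMSO. The 3 interactions, on 4 groups each, tested whether a compound's effect differed between states, and whether the difference between compounds did. The median log2 fold change of all tested genes lay between -0.0094 and 0.0093 in every comparison. Recovery was tested on simulated data with 200 changed genes, the sizes of these libraries and, for each gene, the same spread in every library. There the comparisons of 2 groups recovered 50.7% to 81.8% of 1.5-fold changes and 83.6% to 90.9% of 2-fold changes. The interactions recovered 34.8% to 49.3% and 60% to 75.8%, and 2.52% to 9.47% of calls were false.

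Before the data were examined, 28 gene lists were fixed: p53 targets in 3 groups (arrest and feedback, apoptosis and autophagy, DNA repair and metabolism), mitotic genes repressed by p53 through the DREAM complex, S phase and replication genes, acetyltransferases, deacetylases with acetyl-lysine readers, immunophilins, the bromodomain inhibitor response, MYC targets, hypoxia targets, NF-kB and inflammatory genes, the interferon response, the ATF4 stress response, the unfolded protein response, heat shock genes, NRF2 targets, sterol synthesis, TGF-beta and matrix genes, epithelial genes, immediate early genes, histone genes, oxidative phosphorylation, mitochondrially encoded transcripts, ribosomal proteins and 3 lists of markers of other cell types. With the 3 p53 groups joined as a further list, 27 lists had at least 5 measured members and were tested by camera (limma 3.58.1) with a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, 270 tests in all. Camera with a correlation estimated from the data, and fry, served as alternatives. The markers of lung epithelium and of blood had fewer than 5 measured members and were not tested.

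The tests of genes and lists, the alternatives but for the setting given below as chosen later, and the rule for the genes named were also set before the data were examined. Several tests of explanations were chosen afterwards and are named where they are reported. The rule took EP300, CREBBP, KAT2A, KAT2B, FKBP1A and 1 further gene, left out of the text, in each comparison with DMSO, and the 10 largest rises and falls among called genes with a symbol, at least 5 CPM in the higher group and no overlap between the replicates of both groups. Chance alone gives no overlap for 10% of genes at 3 against 3. The rule also took up to 4 members with the lowest p of each list that passed or had 25% of its members called, and of the joint p53 list everywhere, and the 5 largest differences each way between compounds and in the interactions. Of the genes so taken, the text gives mostly those whose call held with each library left out.

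Alternatives were DESeq2 1.42.0, RLE scaling, no filter on low counts, a mean of at least 1 CPM, all 6 groups in 1 fit, a replicate block, each library left out in turn, and the authors' tables. A setting chosen after seeing the data left out together the libraries in doubt, in the 6 comparisons that hold 2 or more of them. These were the third induced and the third non-induced DMSO library, the second induced PCAF/GCN5 library and the first non-induced PCAF/GCN5 library, which had a large spread from its partners. Alternatives for transcripts and for pseudocounts did not apply, because the files hold raw counts per gene. Overlaps of calls between comparisons that share DMSO libraries were set against 20 simulations of unchanged groups with the same controls. Such groups give few calls, so their overlaps do not measure what shared controls add among changed genes. Each gene had the same simulated spread in every library, so no simulated library stood apart. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.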

Results

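RNA levels were measured by sequencing in H1299 lung cancer cells that make a wild-type p53 fused to FKBP12F36V on induction. AceTAG compounds are heterobifunctional molecules meant to bring an acetyltransferase to a protein that carries this tag. The design asks how AceTAG p300/CBP-1 (the p300/CBP compound) and AceTAG PCAF/GCN5-4 (the PCAF/GCN5 compound) change the transcriptome, with and without the tagged p53. There were 6 groups of 3 libraries. Total counts were 26.4, 25.6 and 9.1 M in non-induced DMSO libraries, 26.4, 21.6 and 19.3 M with the p300/CBP compound and 25.6, 26.6 and 24.3 M with the PCAF/GCN5 compound. In induced cells they were 24.9, 22.4 and 23.6 M with DMSO, 20.2, 22 and 24.2 M with the p300/CBP compound and 29.2, 19.8 and 22.5 M with the PCAF/GCN5 compound. Levels are given as CPM (mean ± SD, n = 3 libraries per group) and changes as log2 fold changes ± SE, with 3 libraries per group, from edgeR quasi-likelihood fits with Benjamini-Hochberg adjusted p.

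The axis of largest variance, with 37.7% of it, parted the libraries by induction and, within each state, by compound. Non-induced DMSO libraries scored 31.7 to 34.3 on it, the non-induced PCAF/GCN5 group 25.4 to 29.9 and the non-induced p300/CBP group 16.2 to 23.4. Induced DMSO libraries scored -12.6 to -11.3, the induced PCAF/GCN5 group -30.9 to -24.7 and the induced p300/CBP group -41.3 to -38.6. The third induced DMSO library stood apart on the next axis, with a score of 59.1 where its partners scored 4.77 and 1.63. Its mitochondrially encoded transcripts made up 0.714% of counts, against 1.84% and 2.14% in its partners. The third non-induced DMSO library, the shallowest, scored -40.8 on PC3 and the second induced PCAF/GCN5 library -37.6 on PC4.

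**Figure D1:**
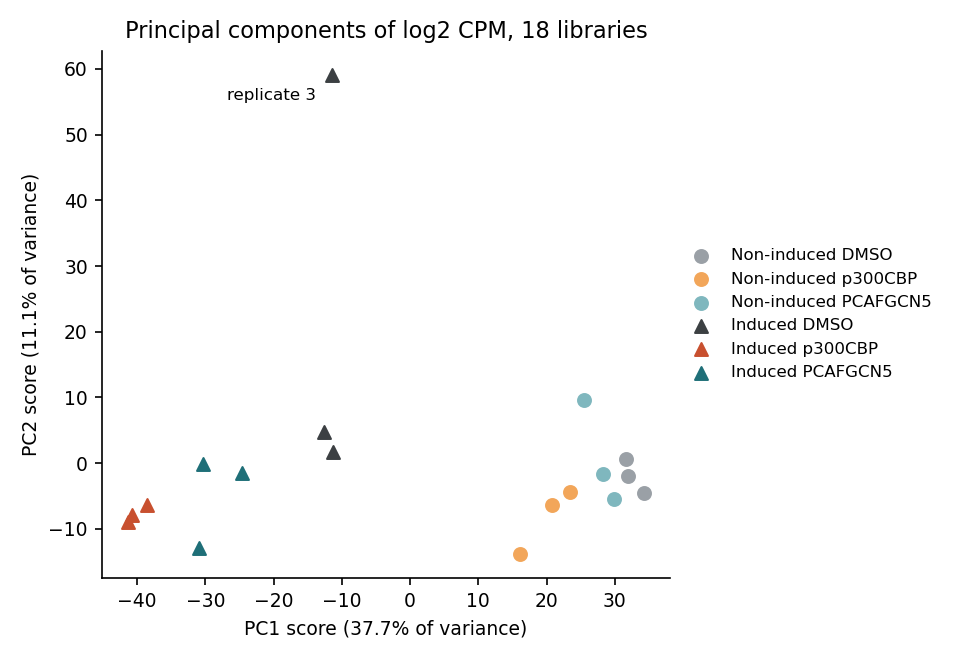
Scores of the 18 libraries on the axes of largest and next largest variance of log2 CPM (37.7% and 11.1% of the variance), with circles for non-induced and triangles for induced cells. The third induced DMSO library lies at 59.1 on the vertical axis, away from its partners at 4.77 and 1.63.

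Many p53 targets rose on induction in DMSO. The labels do not say whether non-induced cells received doxycycline, so this comparison does not part the tagged p53 from the drug. MDM2, the ubiquitin ligase that turns p53 over, rose from 70 ± 1.95 to 582.6 ± 16 CPM (3.06 ± 0.06, adjusted p = 4.33e-08). CDKN1A, which encodes the kinase inhibitor p21, rose from 91.5 ± 4.53 to 352.7 ± 25.9 CPM (1.95 ± 0.07, adjusted p = 1.06e-06). Of the 69 measured p53 targets, 48 rose, 1 fell and 20 did not pass, or 50 and 1 adjusted over the list alone, and the list passed the camera test (median 0.69, adjusted p = 2.69e-75). Large rises in it included the stress cytokine GDF15 (5.13 ± 0.28), the antiproliferative BTG2 (3.89 ± 0.15), the mitochondrial reductase FDXR (3.34 ± 0.23) and the actin regulator CYFIP2 (3.07 ± 0.08). The arrest and feedback group (median 0.70, 14 of 22 rose, 14 adjusted over the list alone, adjusted p = 4.59e-36) included the kinase PLK3. The apoptosis and autophagy group (median 0.86, 18 of 24 rose, 19 adjusted over the list alone, adjusted p = 7.44e-47) included TP53INP1 and DRAM1. In the repair and metabolism group 16 of 23 rose, 17 adjusted over the list alone (median 0.51, adjusted p = 5.45e-23), with the DNA damage sensors DDB2 at 1.62 ± 0.10 and XPC at 1.07 ± 0.07. The 1 target that fell was E2F7 (-0.60 ± 0.09, adjusted p = 0.00335), itself a repressor of E2F-driven genes.

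Genes of cell division fell on induction. In the S phase and replication list 29 of 31 members fell, 30 adjusted over the list alone (median -1.01, adjusted p = 7.38e-72), among them the replication licensing factors CDT1 (-1.35 ± 0.06), MCM4 (-1.30 ± 0.06) and MCM5 (-1.21 ± 0.07). In the mitotic list 35 of 36 fell, 36 adjusted over the list alone (median -0.86, adjusted p = 1.43e-68), among them KIF23, ECT2, CCNA2 and AURKB, which act in mitosis and cytokinesis. The largest falls of all named genes were E2F2 (-1.73 ± 0.09), DTL (-1.46 ± 0.07), TMEM158 (-1.46 ± 0.11) and FAM111B (-1.44 ± 0.09), and BRCA2, which acts in recombination, fell by 1.41. Other lists did not pass, but single members changed. EGR1, an immediate early gene, rose from 70.8 ± 0.459 to 201.5 ± 18.2 CPM and ACTA2, smooth muscle actin, from 3.52 ± 0.434 to 24.4 ± 2.18 CPM. FOSL1, an AP-1 subunit, fell by 1.0 and TFRC, the transferrin receptor, by 0.80. In all, 905 genes rose and 1170 fell of 15055 tested. The count of 2075 was 1372 without the first and 5001 without the third induced DMSO library, and 945, 869 and 1012 without non-induced DMSO library 1, 2 and 3.

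Several of the largest rises on induction lay side by side on the genome. On chromosome 1 between 178094141 and 179098023 (GRCh38) 7 neighbouring genes rose: RASAL2 (1.11 ± 0.09), C1orf220, AL137796.1, AL449106.1, RALGPS2 (3.35 ± 0.07), FAM20B (0.48 ± 0.06) and TOR3A (2.69 ± 0.13). RALGPS2, a Ral exchange factor, went from 9.73 ± 0.149 to 99.2 ± 1.77 CPM, and AL449106.1, which overlaps it on the other strand, from 0.198 ± 0.31 to 54.0 ± 4.35 CPM. C1orf220 went from 0.168 ± 0.0907 to 9.84 ± 1.7 CPM and AL137796.1 from 0.0134 to 1.868 CPM. In non-induced DMSO libraries AL449106.1 had 1, 0 and 5 counts and C1orf220 7, 3 and 1, near the floor of 3 counts. Fitted folds of these 3 genes are therefore not exact, and they are shown only with the figure. On chromosome 20 between 2652593 and 3045747, NOP56 (1.90 ± 0.07), PCED1A (3.79 ± 0.08), VPS16 (2.14 ± 0.12), PTPRA (0.67 ± 0.11) and GNRH2 (2.38 ± 0.38) rose, while IDH3B between them was at -0.11 ± 0.07 (adjusted p = 0.321). NOP56, a nucleolar protein in the MYC list, went from 245.5 ± 16.3 to 914.1 ± 26.3 CPM. The use of strand in counting is not stated, so reads of overlapping neighbours such as PCED1A, VPS16 and PTPRA may not be apart in the files. None of these genes is on a p53 list fixed here.

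**Figure D2:**
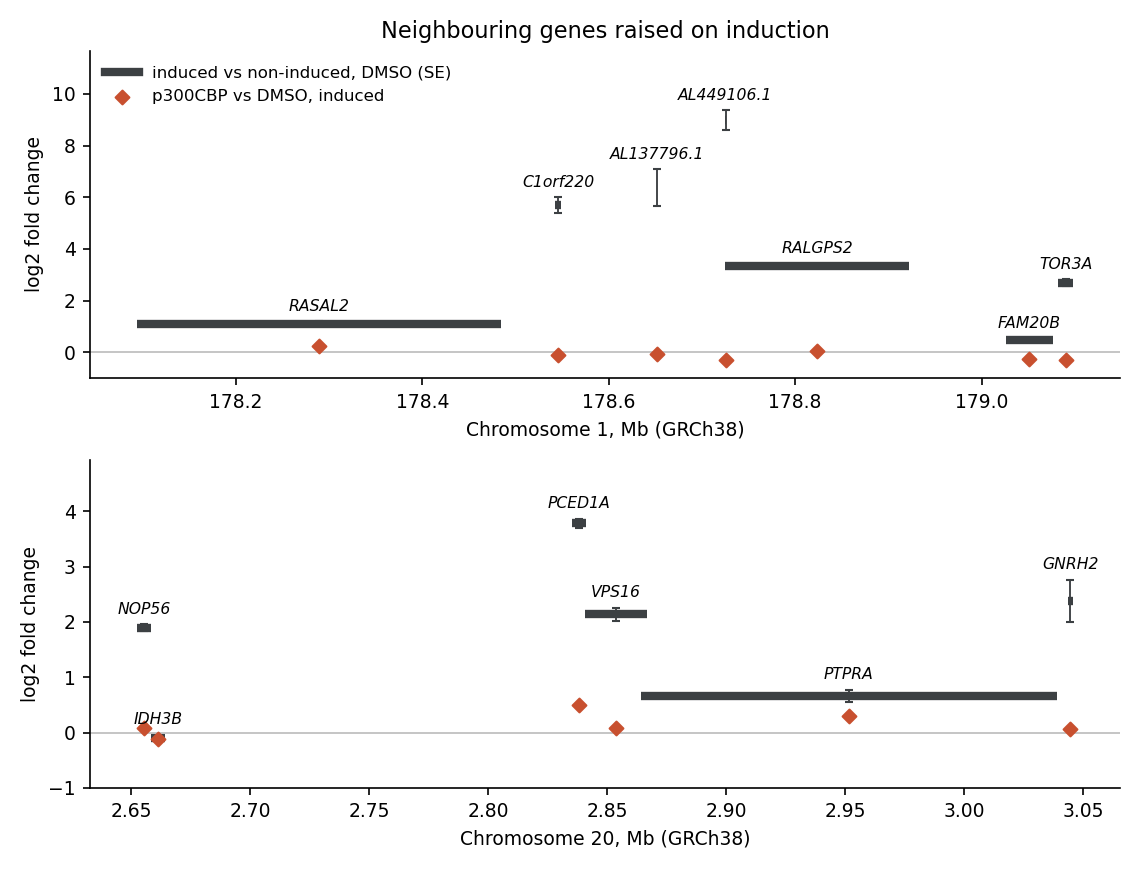
Log2 fold changes of the genes of both regions, drawn at their positions in Mb on GRCh38, with bars spanning each gene for induced against non-induced cells in DMSO (error bars SE) and diamonds for the p300/CBP compound against DMSO in induced cells. AL449106.1 is drawn at 8.98 on induction, a fitted value that rests on 1, 0 and 5 counts in non-induced cells, and at -0.31 with the compound.

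With p53 induced, the p300/CBP compound raised p53 targets further. CDKN1A (ENSG00000124762) rose from 352.7 ± 25.9 to 2371 ± 57.0 CPM (2.75 ± 0.08, adjusted p = 2.34e-07), TP53I3, a quinone reductase linked to oxidative stress, from 78.5 ± 5.14 to 627.7 ± 2.52 CPM (3.0 ± 0.07, adjusted p = 5.32e-08), and TP53I11 from 3.44 ± 0.152 to 96.4 ± 4.30 CPM (4.81 ± 0.09, adjusted p = 1.72e-08). The death receptor FAS rose from 26.5 ± 1.83 to 77.2 ± 2.70 CPM (1.54 ± 0.08) and BBC3, which encodes the pro-apoptotic PUMA, from 15.1 ± 1.40 to 30.5 ± 2.55 CPM (1.02 ± 0.10). MDM2 rose less, from 582.6 ± 16 to 710.3 ± 33.8 CPM (0.29 ± 0.07, adjusted p = 0.0363). Of 69 measured p53 targets 46 rose, 2 fell and 21 did not pass, or 52 and 3 adjusted over the list alone (median 0.57, adjusted p = 3.64e-93). The arrest and feedback group had 15 of 22 risers, 17 adjusted over the list alone (median 0.63, adjusted p = 1.84e-40), such as SESN1 (1.37 ± 0.08), BTG2 (1.15 ± 0.08) and ZMAT3 (1.15 ± 0.07). The apoptosis and autophagy group had 15 of 24, 18 adjusted over the list alone (median 0.54, adjusted p = 4.01e-41), with CYFIP2 at 1.29 ± 0.07 and the death receptor TNFRSF10B at 0.78 ± 0.06. The repair and metabolism group had 16 of 23, 17 adjusted over the list alone (median 0.48, adjusted p = 3.08e-45), with the hydrolase CMBL, the translesion polymerase POLH and the ribonucleotide reductase subunit RRM2B. E2F7 (-0.68 ± 0.10, adjusted p = 0.00506) and BID (-0.39 ± 0.10, adjusted p = 0.0467) were the 2 targets that fell.

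Outside these lists the largest rises were SEPTIN4 (4.47 ± 0.23), a septin whose ARTS isoform promotes apoptosis, the growth factor carrier IGFBP3 (4.44 ± 0.29), NSG1 (3.47 ± 0.23), DPYSL4 (2.97 ± 0.10) and the matrix proteoglycan VCAN (2.67 ± 0.21). ANKRD20A11P, at 2.86 ± 0.32, has near-identical copies in the genome, so its reads may not be its own. Cell cycle lists fell: 25 of 31 S phase genes fell and 1 rose, or 27 and 1 adjusted over the list alone (median -0.69, adjusted p = 2.24e-36), and 30 of 36 mitotic genes fell, 35 adjusted over the list alone (median -0.54, adjusted p = 4.52e-40). MCM2, of the replicative helicase, went from 103.4 ± 8.67 to 54.9 ± 4.14 CPM (-0.91 ± 0.09), and RRM2, of ribonucleotide reductase, changed by -0.76 ± 0.07. NDC80 (-0.70 ± 0.06), TOP2A (-0.68 ± 0.06) and KIF2C (-0.63 ± 0.06) of the mitotic list fell, as did the transcription factors E2F1 (-1.04 ± 0.11) and E2F2 (-1.07 ± 0.11). The 1 S phase gene that rose was PCNA, the polymerase clamp (0.33 ± 0.08, adjusted p = 0.0361).

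The p300/CBP compound moved a few other lists in induced cells, each lost with an estimated correlation. The MYC list passed downward (3 of 30, 9 adjusted over the list alone, median -0.19, adjusted p = 0.000686, but adjusted p = 0.491 with an estimated correlation). The histone list passed upward (2 of 12, 4 adjusted over the list alone, median 0.32, adjusted p = 0.0177, and adjusted p = 0.209 with an estimated correlation), a call that ended without induced DMSO library 2 or 3 (adjusted p = 0.0528 and 0.0976). The epithelial list passed downward (2 of 6, the keratins KRT8 and KRT18, and 3 adjusted over the list alone, median -0.44, adjusted p = 0.02, and adjusted p = 0.192 with an estimated correlation). This ended without the second induced DMSO library (adjusted p = 0.0528) and without the third p300/CBP library (adjusted p = 0.0747), and KRT18 itself missed the threshold without p300/CBP library 2 or 3 (adjusted p = 0.0567 and 0.0601). Mitochondrially encoded transcripts passed upward with 0 of 15 members called by edgeR and 0 adjusted over the list alone (median 0.48, adjusted p = 0.0241, and adjusted p = 0.637 with an estimated correlation), beside the low mitochondrial share of the third induced DMSO library, and ended without the second p300/CBP library (adjusted p = 0.0719). Among the targeted proteins' genes, KAT2B, which encodes PCAF, rose by 0.48 ± 0.10 (adjusted p = 0.0237), but not without p300/CBP library 1, 2 or 3 (adjusted p = 0.0873, 0.115 and 0.138). EP300 (0.29 ± 0.14), CREBBP (0.16 ± 0.10), KAT2A (-0.25 ± 0.09) and FKBP1A (0.03 ± 0.07) did not pass, with adjusted p of 0.26, 0.39, 0.155 and 0.792. In all 441 genes rose and 457 fell of 15019. The 898 became 528 and 3234 without induced DMSO library 1 and 3, and 335, 283 and 263 without p300/CBP library 1, 2 and 3.

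**Figure D3:**
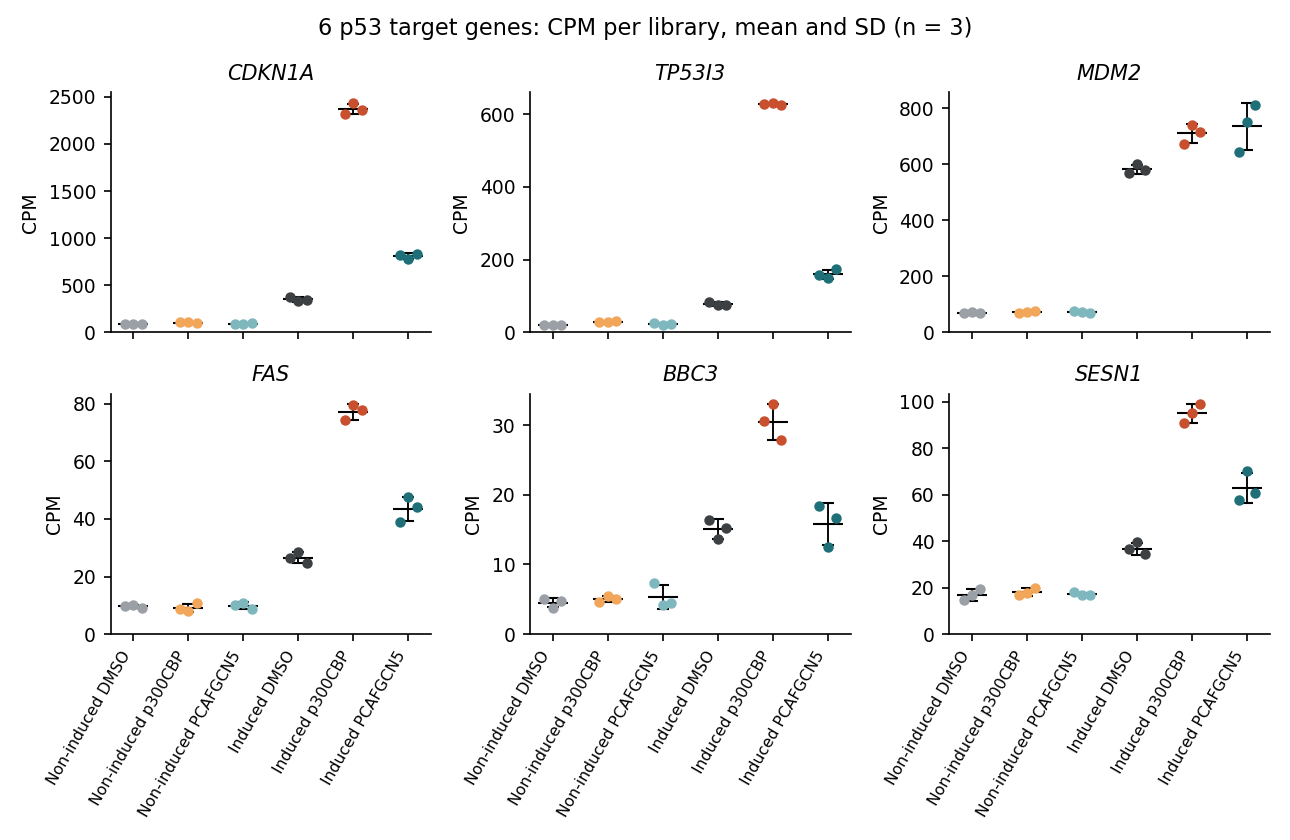
CPM of 6 p53 targets in each library (points) with the mean and SD of each group (n = 3), each vertical axis starting at 0. CDKN1A goes from 352.7 CPM with DMSO to 813.8 with the PCAF/GCN5 and 2371 with the p300/CBP compound in induced cells, while MDM2 goes from 582.6 to 735.6 and 710.3.

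The PCAF/GCN5 compound also raised p53 targets in induced cells, fewer of them past the test. CDKN1A rose from 352.7 ± 25.9 to 813.8 ± 30.6 CPM (1.20 ± 0.08, adjusted p = 0.00027), TP53I11 from 3.44 ± 0.152 to 26.3 ± 1.06 CPM (2.93 ± 0.12, adjusted p = 2.47e-06) and TP53I3 from 78.5 ± 5.14 to 160.2 ± 12.6 CPM (1.03 ± 0.08, adjusted p = 0.000377). IGFBP3 rose from 0.674 ± 0.457 to 13.6 ± 3 CPM (4.33 ± 0.33, adjusted p = 0.000348). Other large rises were NSG1 (3.17 ± 0.28), the axon guidance genes DRAXIN (2.78 ± 0.24) and PLXNB3 (2.40 ± 0.21), VCAN (2.16 ± 0.21) and the glutaminase GLS2 (2.06 ± 0.21), itself a p53 target. Of 70 measured p53 targets 16 rose, 0 fell and 54 did not pass by edgeR, or 43 rose and 1 fell adjusted over the list alone (median 0.35, adjusted p = 4.18e-60). The arrest group had 5 of 23 risers, 16 adjusted over the list alone (median 0.34, adjusted p = 7.6e-29), the apoptosis group 6 of 24, 12 adjusted over the list alone (median 0.33, adjusted p = 1.22e-20), and the repair group 5 of 23, 15 adjusted over the list alone (median 0.35, adjusted p = 5.36e-35). BTG2 (1.08 ± 0.09), ZMAT3 (0.93 ± 0.10), CYFIP2 (0.92 ± 0.07) and POLH (0.75 ± 0.09) were among them. MDM2 was at 0.33 ± 0.10 (adjusted p = 0.393). ANGPTL4, a secreted lipase inhibitor on the hypoxia list, was the 1 gene that fell, from 147.7 ± 16.3 to 66.8 ± 5.31 CPM (-1.15 ± 0.10, adjusted p = 0.000509).

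Cell cycle lists passed downward with the PCAF/GCN5 compound in induced cells, with 0 members called by edgeR. The S phase list had a median of -0.34 (0 of 31 fell, 18 adjusted over the list alone, adjusted p = 2.86e-14, but adjusted p = 0.205 with an estimated correlation), with MCM2 at -0.48 ± 0.12 and GINS2 at -0.62 ± 0.13. The mitotic list had a median of -0.13 (0 of 36, 0 adjusted over the list alone, adjusted p = 1.16e-05, and adjusted p = 0.385 with an estimated correlation) and MYC targets one of -0.15 (0 of 30, 0 adjusted over the list alone, adjusted p = 2.5e-05, and adjusted p = 0.257 with an estimated correlation). The hypoxia list passed downward (1 of 25, ANGPTL4, and 1 adjusted over the list alone, median -0.10, adjusted p = 0.0141, and adjusted p = 0.24 with an estimated correlation), but not without the second induced DMSO library (adjusted p = 0.0509). The histone list passed upward (0 of 12, 1 adjusted over the list alone, median 0.27, adjusted p = 0.0133, and adjusted p = 0.24 with an estimated correlation), but not without the first PCAF/GCN5 library (adjusted p = 0.0511). The ribosomal protein list passed downward (0 of 30, 0 adjusted over the list alone, median -0.09, adjusted p = 0.046, and adjusted p = 0.541 with an estimated correlation), but not without the first induced DMSO library (adjusted p = 0.093) or PCAF/GCN5 library 1 or 3 (adjusted p = 0.112 and 0.11). Neither KAT2B (0.31 ± 0.10), EP300 (0.19 ± 0.14), CREBBP (0.15 ± 0.12), KAT2A (-0.11 ± 0.10) nor FKBP1A (0.08 ± 0.08) passed, with adjusted p of 0.45, 0.626, 0.655, 0.693 and 0.732. In all 51 genes rose and 1 fell of 15078 tested, where 1530 had an unadjusted p below 0.05. Other settings called far more falls, 349 beside 192 rises with no filter on low counts and 124 beside 228 with all 6 groups in 1 fit. The 52 became 114 without the third induced DMSO library and 30, 31 and 29 without PCAF/GCN5 library 1, 2 and 3. Falls were 2 without the second and 4 without the third induced DMSO library.

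Set against each other in induced cells, the p300/CBP compound gave higher levels of many p53 targets than the PCAF/GCN5 compound. The doses are not in the labels, so the compounds are compared only as applied. TP53I3 was higher by 1.97 ± 0.06 (adjusted p = 4.45e-12), TP53I11 by 1.87 ± 0.06 (adjusted p = 1.46e-11), CDKN1A by 1.54 ± 0.05 (adjusted p = 1.46e-11), BBC3 by 0.94 ± 0.11 (adjusted p = 0.000147) and FAS by 0.83 ± 0.07 (adjusted p = 3.96e-06). Of 69 p53 targets 29 were higher, 4 lower and 36 did not pass, or 40 and 5 adjusted over the list alone (median 0.24, adjusted p = 1.5e-41). By group, 8 of 23 arrest genes (13 adjusted over the list alone, median 0.24, adjusted p = 3.95e-17), 11 of 23 apoptosis genes (15 adjusted over the list alone, median 0.27, adjusted p = 6.91e-21) and 10 of 23 repair genes (13 adjusted over the list alone, median 0.22, adjusted p = 1.69e-20) were higher. Among the lower ones were E2F7 (-0.48 ± 0.09), BID (-0.40 ± 0.10) and TRIAP1 (-0.31 ± 0.07). For some targets no difference passed: MDM2 differed by -0.05 (95% interval -0.204 to 0.101), BTG2 by 0.07 (-0.0587 to 0.191) and GLS2 by -0.17 (-0.44 to 0.104). The same held for EP300 (0.09, -0.0261 to 0.212), CREBBP (0.00, -0.162 to 0.157), KAT2A (-0.15, -0.298 to 0.00614) and FKBP1A (-0.05, -0.161 to 0.0584), and for KAT2B the interval of 0.0416 to 0.279 lay above 0 with an adjusted p of 0.143.

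**Figure D4:**
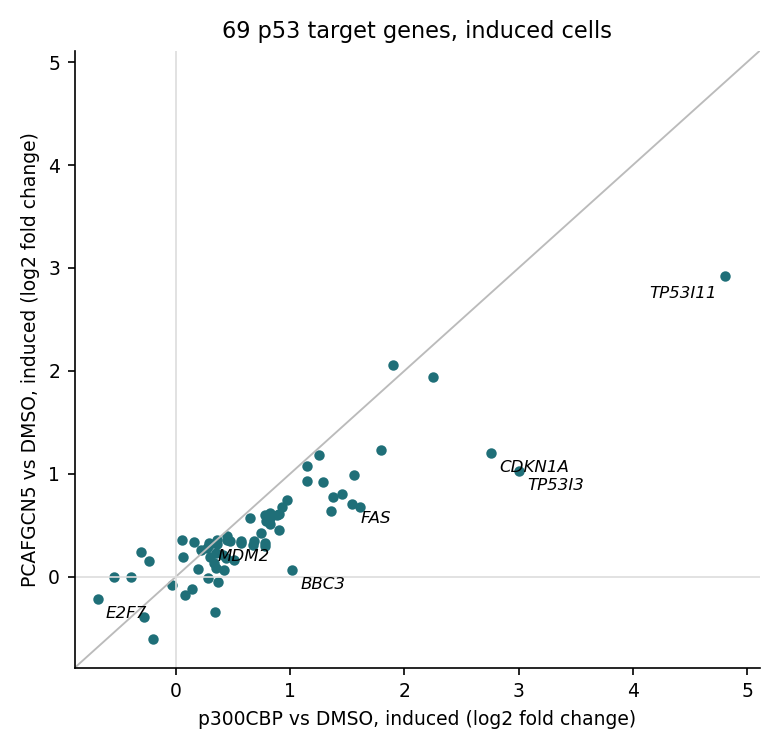
Log2 fold changes of 69 p53 targets in induced cells, with the p300/CBP compound on the horizontal and the PCAF/GCN5 compound on the vertical axis, both against the same DMSO libraries, and the diagonal of equal change in grey. 56 genes lie below the diagonal, CDKN1A at 2.75 and 1.20, and 13 above it, MDM2 at 0.29 and 0.33.

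Genes of cell division were lower with the p300/CBP than with the PCAF/GCN5 compound in induced cells. In the mitotic list 33 of 36 were lower, 35 adjusted over the list alone (median -0.41, adjusted p = 2.74e-59, but adjusted p = 0.062 with an estimated correlation), among them TOP2A (-0.57 ± 0.06), TPX2 (-0.45 ± 0.06) and CCNB1 (-0.42 ± 0.05). In the S phase list 17 of 31 were lower, 26 adjusted over the list alone (median -0.33, adjusted p = 4.25e-23, and adjusted p = 0.0702 with an estimated correlation), among them CDC6 (-0.63 ± 0.09) and MCM4 (-0.47 ± 0.06). The TGF-beta and matrix list passed downward (4 of 24, 4 adjusted over the list alone, median -0.12, adjusted p = 4.36e-05, and adjusted p = 0.0702 with an estimated correlation), with ACTA2 at 30.3 ± 1.6 against 51.3 ± 2.62 CPM (-0.76 ± 0.07). The immediate early list passed downward (3 of 25, 4 adjusted over the list alone, median -0.07, adjusted p = 0.00378, and adjusted p = 0.202 with an estimated correlation), among them PHLDA1 (-0.40 ± 0.05) and SPRY4 (-0.38 ± 0.06). The ATF4 list passed upward (4 of 26, 5 adjusted over the list alone, median 0.016, adjusted p = 0.0317, and adjusted p = 0.472 with an estimated correlation), with ATF3 at 0.60 ± 0.09 and SESN2 at 0.33 ± 0.05, but not without the first or second p300/CBP library (adjusted p = 0.082 and 0.0544) or the third PCAF/GCN5 library (adjusted p = 0.172). Mitochondrially encoded transcripts passed upward as a list (0 of 15 by edgeR, 0 adjusted over the list alone, median 0.18, adjusted p = 0.00712, and adjusted p = 0.67 with an estimated correlation), but not without the second p300/CBP library (adjusted p = 0.116) or the third PCAF/GCN5 library (adjusted p = 0.561). In all 280 genes were higher and 337 lower of 14983. The 617 became 309, 254 and 236 without p300/CBP library 1, 2 and 3, and 1098 without the second PCAF/GCN5 library.

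Without induction, the p300/CBP compound lowered cell cycle genes, while most p53 targets did not pass. All 31 S phase genes fell, 31 adjusted over the list alone (median -0.61, adjusted p = 1.22e-75, but adjusted p = 0.103 with an estimated correlation). MCM2 went from 240.8 ± 3.77 to 138.1 ± 31.1 CPM (-0.79 ± 0.10, adjusted p = 8.81e-05), PCNA from 286.0 ± 7.43 to 199.4 ± 10.0 CPM (-0.51 ± 0.05, adjusted p = 1.73e-05). TYMS, thymidylate synthase, was at -0.57 ± 0.06. In the mitotic list 35 of 36 fell, 35 adjusted over the list alone (median -0.46, adjusted p = 1.82e-66, and adjusted p = 0.103 with an estimated correlation), with CDK1 going from 133.4 ± 5.42 to 88.5 ± 6.74 CPM (-0.58 ± 0.06). Large falls also took in the cell cycle kinase PKMYT1 (-0.86 ± 0.09), the transcription factors E2F2 (-0.90 ± 0.10), E2F7 (-0.83 ± 0.09) and TP73 (-0.79 ± 0.11), and DTL (-0.79 ± 0.10), which marks CDT1 for destruction. MYC targets fell (24 of 30, 27 adjusted over the list alone, median -0.24, adjusted p = 6.68e-18, and adjusted p = 0.22 with an estimated correlation), among them MRTO4 and PA2G4, which act in ribosome assembly and growth. Of 67 p53 targets 8 rose, 3 fell and 56 did not pass, or 13 and 6 adjusted over the list alone, and the list missed the threshold (median 0.080, adjusted p = 0.166). TP53I3 (0.46 ± 0.08) and TP53INP1 (0.61 ± 0.12) rose and the nuclease AEN fell by 0.46. CDKN1A rose by 0.20 ± 0.06 (adjusted p = 0.0277), but not without non-induced DMSO library 1, 2 or 3 (adjusted p = 0.104, 0.0963 and 0.122) or the second p300/CBP library (adjusted p = 0.157).

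The sterol, histone and NRF2 lists passed upward with the p300/CBP compound without induction, through a minority of their members. In the sterol list 7 of 26 rose, 12 adjusted over the list alone (median 0.12, adjusted p = 7.3e-06, but adjusted p = 0.103 with an estimated correlation). SCD, a fatty acid desaturase, went from 789.9 ± 26.4 to 1051 ± 33.8 CPM (0.43 ± 0.05), and TM7SF2 and INSIG1 changed by 0.52 ± 0.08 and 0.36 ± 0.05. In the histone list 5 of 12 rose, 7 adjusted over the list alone (median 0.42, adjusted p = 2.75e-06, and adjusted p = 0.173 with an estimated correlation), with HIST1H2BD at 0.74 ± 0.13 and HIST1H2AC at 0.58 ± 0.09. The NRF2 list passed upward (3 of 20, 3 adjusted over the list alone, median 0.11, adjusted p = 0.00202, and adjusted p = 0.131 with an estimated correlation). These were the ferritin chains FTH1 (0.37 ± 0.05) and FTL (0.29 ± 0.05) and the quinone reductase NQO1 (0.23 ± 0.04). Mitochondrially encoded transcripts passed upward as a list (3 of 15, 7 up and 1 down adjusted over the list alone, median 0.17, adjusted p = 0.000599, and adjusted p = 0.385 with an estimated correlation), but not without the first p300/CBP library (adjusted p = 0.0793).

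Weaker lists in the same comparison depended on single libraries. The hypoxia list passed downward (6 of 25, 8 adjusted over the list alone, median -0.13, adjusted p = 0.0487, and adjusted p = 0.378 with an estimated correlation), among them BNIP3 (-0.47 ± 0.06), the glucose transporter SLC2A1 (-0.31 ± 0.06) and hexokinase HK2 (-0.40 ± 0.07). The hypoxia call ended without the first or second non-induced DMSO library (adjusted p = 0.142 and 0.0917) and without p300/CBP library 1 or 3 (adjusted p = 0.0793 and 0.0599). The heat shock list passed downward (2 of 16, 3 adjusted over the list alone, median -0.09, adjusted p = 0.0478, and adjusted p = 0.385 with an estimated correlation), but not without non-induced DMSO library 1, 2 or 3 (adjusted p = 0.114, 0.055 and 0.0538) or p300/CBP library 1 or 3 (adjusted p = 0.0793 and 0.0705). The arrest group of p53 targets passed upward (4 of 22 up and 1 down, 6 and 1 adjusted over the list alone, median 0.14, adjusted p = 0.0478, and adjusted p = 0.22 with an estimated correlation). This was lost without non-induced DMSO library 1 or 3 (adjusted p = 0.0503 and 0.055) and without p300/CBP library 1, 2 or 3 (adjusted p = 0.0793, 0.0567 and 0.0599). KAT2B rose by 0.26 ± 0.07 (adjusted p = 0.0168), but not without non-induced DMSO library 1, 2 or 3 (adjusted p = 0.0844, 0.0907 and 0.0689) or the second p300/CBP library (adjusted p = 0.0581). EP300 (0.17 ± 0.05), CREBBP (0.08 ± 0.05), KAT2A (-0.22 ± 0.07) and FKBP1A (-0.08 ± 0.05) did not pass (adjusted p = 0.0566, 0.395, 0.0502 and 0.31). In all 512 genes rose and 966 fell of 14943, only 11 and 6 of them by 1 or more on the log2 scale. The 1478 became 581, 527 and 795 without non-induced DMSO library 1, 2 and 3, and 2384 and 703 without the first and second p300/CBP library.

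The PCAF/GCN5 compound changed 3 genes of 15100 by edgeR in non-induced cells. SAP18, a subunit of a histone deacetylase complex, rose from 66.2 ± 5.99 to 93.3 ± 6.09 CPM (0.50 ± 0.07, adjusted p = 0.0175), the ribosomal stalk gene RPLP2 went from 394.6 ± 11.3 to 294.8 ± 19.9 CPM (-0.42 ± 0.06, adjusted p = 0.0128), and BOLA2B went from 1.04 ± 0.266 CPM to no counts. BOLA2B was outside the rule for named genes and was chosen after its values were seen; it has a near-identical copy, so its reads may not be its own. The mitotic list passed downward (0 of 36, 19 adjusted over the list alone, median -0.15, adjusted p = 2.74e-26, but adjusted p = 0.424 with an estimated correlation), as did the S phase list (0 of 31, 12 adjusted over the list alone, median -0.14, adjusted p = 2.67e-16, and adjusted p = 0.424 with an estimated correlation). CDC20 was at -0.27 ± 0.07, MCM2 at -0.24 ± 0.06 and CDT1 at -0.25 ± 0.07, each with an adjusted p of 0.767. Sterol genes passed upward (0 of 26, 0 adjusted over the list alone, median 0.050, adjusted p = 0.0188, and adjusted p = 0.424 with an estimated correlation), but not without the third non-induced DMSO library (adjusted p = 0.113) or the third PCAF/GCN5 library (adjusted p = 0.0839). Mitochondrially encoded transcripts did not pass (adjusted p = 0.658, downward), but they passed upward without the first PCAF/GCN5 library (adjusted p = 3.29e-27) and downward without the second (adjusted p = 0.0026). Of 66 p53 targets 0 passed by edgeR (median 0.043, adjusted p = 0.153), with CDKN1A at 93.4 ± 6.48 against 91.5 ± 4.53 CPM. EP300 (-0.01 ± 0.06), CREBBP (-0.06 ± 0.05), KAT2A (-0.10 ± 0.07), KAT2B (0.09 ± 0.05) and FKBP1A (-0.12 ± 0.07) did not pass (adjusted p = 0.991, 0.848, 0.808, 0.798 and 0.803). An unadjusted p below 0.05 was found for 959 genes, and DESeq2 called 6. Without non-induced DMSO library 1, 2 or 3 or the third PCAF/GCN5 library edgeR called 0 genes, and 17 and 1 without the first and second PCAF/GCN5 library. SAP18 was lost in 5 of these settings and RPLP2 in 4.

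Compared directly without induction, S phase genes were lower with the p300/CBP than with the PCAF/GCN5 compound. Of 31, 22 were lower, 31 adjusted over the list alone (median -0.48, adjusted p = 7.98e-56, but adjusted p = 0.194 with an estimated correlation), among them RFC4 (-0.56 ± 0.09), POLA1 (-0.45 ± 0.07) and FEN1 (-0.60 ± 0.10), which act at the replication fork. Of 36 mitotic genes 7 were lower, 30 adjusted over the list alone (median -0.26, adjusted p = 2.46e-28, and adjusted p = 0.194 with an estimated correlation), and of 30 MYC targets 2, or 16 adjusted over the list alone (median -0.21, adjusted p = 1.11e-14, and adjusted p = 0.194 with an estimated correlation). The histone list passed upward (2 of 14, 5 adjusted over the list alone, median 0.20, adjusted p = 1.81e-05, and adjusted p = 0.194 with an estimated correlation), as did the NRF2 list (1 of 20, FTH1, and 2 adjusted over the list alone, median 0.09, adjusted p = 0.0035, and adjusted p = 0.194 with an estimated correlation). Of 68 p53 targets 0 were higher and 1, E2F7, lower, or 3 and 1 adjusted over the list alone (median 0.0033, adjusted p = 0.647). CDKN1A differed by 0.18 (95% interval 0.0261 to 0.332, adjusted p = 0.254) and MDM2 by 0.02 (-0.122 to 0.166). In all 24 genes were higher and 141 lower of 15131. The 165 became 310, 1 and 19 without p300/CBP library 1, 2 and 3, and 287, 1 and 47 without PCAF/GCN5 library 1, 2 and 3. Without the second library of either group, RFC4, POLA1 and FEN1 missed the threshold (adjusted p = 0.145 and 0.0821 for each).

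Other lists in this comparison rested on few libraries. The sterol list passed upward (1 of 26, SCD, and 1 adjusted over the list alone, median 0.066, adjusted p = 0.00593, and adjusted p = 0.194 with an estimated correlation), but not without the first p300/CBP library (adjusted p = 0.0712). The bromodomain inhibitor response passed upward (1 of 13, HIST1H2BD, and 2 adjusted over the list alone, median 0.14, adjusted p = 0.0122, and adjusted p = 0.194 with an estimated correlation), but not without the first p300/CBP or the first PCAF/GCN5 library (adjusted p = 0.0924 and 0.0901). This list shares several histone genes, HIST1H2BD among them, with the histone list, so the 2 calls are not independent. The heat shock list passed downward (1 of 16, HSPD1, and 1 adjusted over the list alone, median -0.11, adjusted p = 0.0296, and adjusted p = 0.457 with an estimated correlation), but not without p300/CBP library 1 or 3 (adjusted p = 0.0861 and 0.16) or PCAF/GCN5 library 1 or 3 (adjusted p = 0.0589 and 0.133). Mitochondrially encoded transcripts passed upward as a list (1 of 15, MT-RNR1, and 2 up and 1 down adjusted over the list alone, median 0.20, adjusted p = 0.00534, and adjusted p = 0.73 with an estimated correlation). That call ended without the first p300/CBP library (adjusted p = 0.145) and turned direction without the first PCAF/GCN5 library (adjusted p = 0.496).

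**Figure D5:**
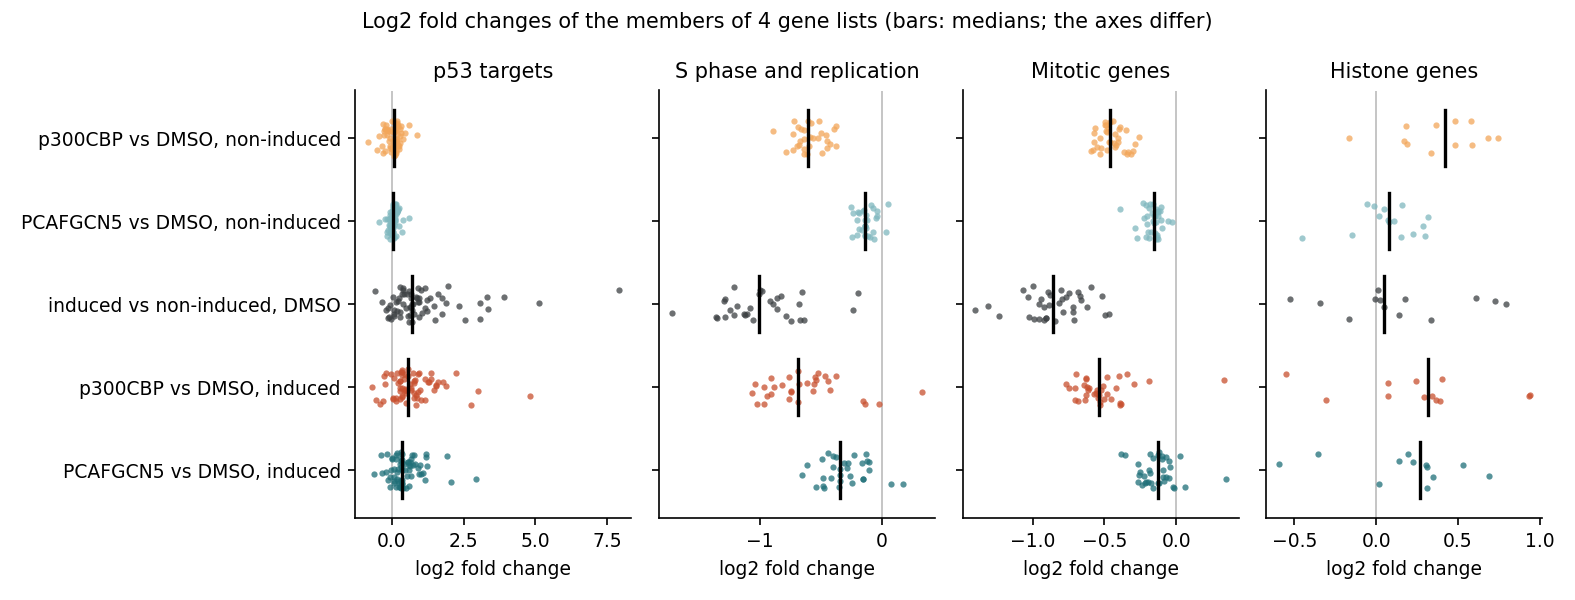
Log2 fold changes of the measured members of 4 lists (points) and their medians (bars) in the 5 comparisons with a DMSO or non-induced control, with horizontal axes that differ between panels. The S phase medians are -0.61 and -0.14 with the p300/CBP and PCAF/GCN5 compound without induction, and those of p53 targets 0.080 and 0.043.

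Whether a compound acted differently in induced cells was tested by interactions, where a positive difference is a log2 fold change that lay higher there. Like the comparison on induction, they do not part the tagged p53 from doxycycline. For the p300/CBP compound 28 of 69 p53 targets had a positive and 0 a negative difference by edgeR, 48 and 0 adjusted over the list alone (median 0.52, adjusted p = 9.44e-82). TP53I3 (2.56 ± 0.08, adjusted p = 4.46e-11), CDKN1A (2.56 ± 0.09, adjusted p = 8.99e-11), FAS (1.63 ± 0.14), SESN1 (1.24 ± 0.14), CMBL (1.47 ± 0.14) and KITLG (1.99 ± 0.22), which encodes stem cell factor, were among them. In the arrest group 9 of 22 differed, 16 adjusted over the list alone (adjusted p = 1.11e-38), in the apoptosis group 10 of 24, 16 adjusted over the list alone (adjusted p = 4.28e-40), and in the repair group 9 of 23, 16 adjusted over the list alone (adjusted p = 3.07e-33). The sterol list passed downward (1 of 26, and 4 adjusted over the list alone, median -0.25, adjusted p = 2.21e-06). In all 200 genes of 15618 differed, 170 of them upward. The count was 432 without the third induced DMSO library, 125 without the second induced p300/CBP library and 123 without the first non-induced DMSO library.

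For the PCAF/GCN5 compound 6 of 70 p53 targets had a positive difference, 29 up and 2 down adjusted over the list alone (median 0.32, adjusted p = 9.33e-34). They were CDKN1A (1.17 ± 0.10, adjusted p = 2.7e-05), TP53I3 (0.91 ± 0.12), ZMAT3 (0.87 ± 0.12), POLH (0.85 ± 0.12), CYFIP2 (0.79 ± 0.10) and TP53I11. TP53I11 (2.69 ± 0.41, adjusted p = 0.0117) missed the threshold without non-induced DMSO library 2 or 3 (adjusted p = 0.359 and 0.0543). IGFBP3 (4.83 ± 0.57) and the phospholipid transfer protein PLTP (1.40 ± 0.12) also had a positive difference. That of ANGPTL4, which fell in induced cells, was negative (-1.32 ± 0.12). In all 11 of 15813 genes differed, where 1148 had an unadjusted p below 0.05. The count was 18 without the first and 24 without the third induced DMSO library. The difference between the compounds, p300/CBP minus PCAF/GCN5, lay higher in induced cells for 10 of 70 p53 targets, 24 up and 1 down adjusted over the list alone (median 0.17, adjusted p = 1.82e-22), such as TP53I3 (1.63 ± 0.10), CDKN1A (1.36 ± 0.09), FAS (0.93 ± 0.15) and CMBL (0.78 ± 0.08). Outside that list DPYSL4 (2.24 ± 0.28), FAM43A (1.90 ± 0.17) and SAC3D1 (1.71 ± 0.14) showed it, as did NME1 (0.75 ± 0.10) of the MYC list and PCNA (0.52 ± 0.08) of the S phase list. For SPRY4, an antagonist of growth factor signalling, it lay lower in induced cells (-0.45 ± 0.08). In all 51 of 15656 genes differed, 40 of them upward.

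The lists that passed in none of the 10 comparisons were acetyltransferases (lowest adjusted p = 0.0862), deacetylases with acetyl-lysine readers (0.382), immunophilins (0.0922), NF-kB and inflammatory genes (0.187), the interferon response (0.182), nuclear oxidative phosphorylation genes (0.0572) and markers of endothelium, fibroblasts and neural cells (0.202, with 5 to 7 measured). Markers of blood (18 genes) and lung epithelium (16 genes) had too few measured members to test, and their highest levels over all libraries were 3.07 CPM for ITGAM and 3.60 CPM for AGER.

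Calls were compared between comparisons. In induced cells 45 genes rose and 1 fell with both compounds, and no gene moved in opposite directions. Independent calls would give 1.42 and 0.0308. A simulation of unchanged groups gave at most 0 and 1, but with no changed genes it yields few calls in either comparison. It cannot show how many shared calls the common DMSO libraries add. The log2 fold changes of both compounds had a Pearson correlation of 0.743 across genes, which are not independent replicates, against 0.504 in simulations of unchanged groups that share the DMSO libraries, and a covariance of 0.0807 against 0.0215. Across the 69 p53 targets the Spearman correlation was 0.864, against at most 0.573 in the simulations. In non-induced cells 1 gene, BOLA2B, fell with both compounds (0.13 by independence), no more than the highest of the simulations (1). The Pearson correlation was 0.537 against 0.536 in the simulations, with a covariance of 0.0287 against 0.0167 (at most 0.01803 in a simulation). The 3 DMSO libraries of a state cannot be split between the compounds, so part of each excess may come from the shared controls. For the p300/CBP compound 51 genes rose and 312 fell in both states (14 and 30.2 by independence), 1 rose without and fell with induction and 4 did the reverse, at a Pearson correlation of 0.326 across genes. For the PCAF/GCN5 compound 0 genes changed in both states by edgeR, from 3 and 52 calls, with 959 and 1530 genes at an unadjusted p below 0.05. The 46 shared in induced cells became 107 without the third induced DMSO library, and 29, 29 and 27 without PCAF/GCN5 library 1, 2 and 3. The 363 of the p300/CBP compound became 234 and 902 without induced DMSO library 1 and 3, and 132, 108 and 88 without induced p300/CBP library 1, 2 and 3. BOLA2B was not shared without any one non-induced DMSO library or non-induced PCAF/GCN5 library 2 or 3, and 6 genes were shared without the first.

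The rises on induction and with a compound were compared too, with the induced DMSO libraries on both sides. The simulated overlaps here hold no changed genes either and have the same limit. Of 441 genes raised by the p300/CBP compound in induced cells 46 were on the p53 lists, and of 414 tested on induction 155 also rose and 1 fell there (25.3 rises by independence, at most 0 in a simulation). Of the 457 it lowered, 305 also fell on induction and 13 rose (35.8 falls by independence, at most 0 in a simulation). Of 51 genes raised by the PCAF/GCN5 compound 16 were on the p53 lists, and 31 of 43 tested also rose on induction (2.62 by independence, at most 0 in a simulation). ANGPTL4, lowered by the PCAF/GCN5 compound, had risen on induction. Without induction the p300/CBP compound and induction shared 176 rises and 590 falls (30 and 76.5 by independence, at most 1 and 1 in a simulation), with the non-induced DMSO libraries on both sides. Their Pearson correlation across genes was 0.496 against 0.533 in the simulations, and their covariance 0.0503 against 0.0185 (at most 0.01946 in a simulation).

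The authors' DESeq2 tables drew on counts beyond those deposited for these 18 libraries, whether of further libraries or of another counting. Without induction they listed 1614 genes with an adjusted p below 0.05 for the p300/CBP and 11 for the PCAF/GCN5 compound. In induced cells they listed 2748 and 1223. For the PCAF/GCN5 compound in induced cells 420 of them were higher and 803 lower. Of these, 1317, 2, 872 and 31 were also called here, all in the same direction.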

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

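For the third induced DMSO library the tests of depth, gene length, GC content as the whole cause and mislabelling were chosen only after the result was seen, as were those of residual p53 and of the growth state of the DMSO cultures, the test of a local effect on neighbouring genes, its repeat over whole windows and the tests of clusters among genes raised by 1 or more. The other tests in this part were set before.

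The p300/CBP compound's response differed between induced and non-induced cells in 200 genes by a test of the difference, and so did that of 4 p53 lists, with median differences of 0.52 for all targets, 0.496 for arrest and feedback, 0.551 for apoptosis and autophagy and 0.515 for DNA repair and metabolism. IGFBP3 differed by 4.95, TP53I11 by 4.60, SEPTIN4 by 4.55, TP53I3 by 2.56, CDKN1A by 2.56, FAS by 1.63 and CYFIP2 by 1.19. NSG1 and ABCA12 had no counts in non-induced cells with this compound, so their levels of 8.312 and 5.569 CPM in induced cells with it are given in place of a fold. NSG1 missed the threshold without non-induced DMSO library 1 or 3 (adjusted p = 0.0639 and 0.0836), and ABCA12 without each of the 12 libraries but the third induced DMSO one (adjusted p = 0.051 to 0.304). LINC02593 (-1.27), ABCD2 (-0.92) and MYH15 (-0.89) differed the other way, as did AC009005.1 (-0.97) and CNIH3 (-0.88). AC009005.1 was lost without each library but induced DMSO 2 and 3 and the third induced p300/CBP ones (adjusted p = 0.0526 to 0.126), and CNIH3 without each but induced DMSO 2 and 3 and the first non-induced p300/CBP ones (adjusted p = 0.0605 to 0.108).

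The same test put other lists past the threshold for the p300/CBP compound. The sterol list passed downward (median difference -0.248, adjusted p = 2.21e-06), with a median of 0.116 without and -0.0581 with induction. The ATF4 list passed upward (0.083, 4 of 26 adjusted over the list alone, adjusted p = 0.00565, and adjusted p = 0.257 with an estimated correlation). The epithelial list passed downward (-0.205, 2 of 9 adjusted over the list alone, adjusted p = 0.0119, and adjusted p = 0.073 with an estimated correlation), but not without the third induced p300/CBP library (adjusted p = 0.0547). The immediate early list also passed downward (-0.049, 1 up and 5 down of 25 adjusted over the list alone, adjusted p = 0.0119, and adjusted p = 0.134 with an estimated correlation), but not without the first induced DMSO library (adjusted p = 0.0562). Mitotic genes had a median difference of -0.0484 (0 of 36 adjusted over the list alone, adjusted p = 0.0363, and adjusted p = 0.754 with an estimated correlation). That call ended without the second induced DMSO library (adjusted p = 0.236), induced p300/CBP library 2 or 3 (adjusted p = 0.0583 and 0.148), the first non-induced DMSO library (adjusted p = 0.135) and the first or second non-induced p300/CBP library (adjusted p = 0.443 and 0.074). Mitochondrially encoded transcripts had 0.359 (0 of 15 adjusted over the list alone, adjusted p = 0.0328, and adjusted p = 0.754 with an estimated correlation). Without the third induced DMSO library their direction turned (adjusted p = 0.74), and the call ended without the second induced p300/CBP, the second non-induced DMSO or the third non-induced p300/CBP library (adjusted p = 0.133, 0.053 and 0.109).

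For the PCAF/GCN5 compound the response differed between the states in 11 genes and in the p53 lists, with medians of 0.321 for all targets, 0.429 for arrest (12 of 23 adjusted over the list alone), 0.336 for apoptosis (9 up and 2 down of 24) and 0.29 for repair (9 of 23). IGFBP3 differed by 4.83, PLTP by 1.40, CDKN1A by 1.17, TP53I3 by 0.91, ZMAT3 by 0.87, CYFIP2 by 0.79 and ANGPTL4 by -1.32. TP53I11 differed by 2.69, but not without non-induced DMSO library 2 or 3 (adjusted p = 0.359 and 0.0543), and VCAN by 2.12, lost without each library but the 3 induced DMSO ones (adjusted p = 0.0524 to 0.253). S phase genes had a median of -0.171 (0 of 31 adjusted over the list alone, adjusted p = 0.000189, and adjusted p = 0.43 with an estimated correlation) and MYC targets one of -0.177 (0 of 30 adjusted over the list alone, adjusted p = 0.00222, and adjusted p = 0.392 with an estimated correlation). The unfolded protein response had -0.15 (0 of 18 adjusted over the list alone, adjusted p = 0.0107, and adjusted p = 0.392 with an estimated correlation), but not without the first induced PCAF/GCN5 library (adjusted p = 0.052).

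The difference between the compounds itself differed between the states in 51 genes and in the p53 lists, with medians of 0.169 for all targets, 0.123 for arrest (6 up and 1 down of 23 adjusted over the list alone), 0.244 for apoptosis (10 of 24) and 0.234 for repair (8 of 23). ANKRD20A11P differed by 3.11, DPYSL4 by 2.24, FAM43A by 1.90, SAC3D1 by 1.71, TP53I3 by 1.63, CDKN1A by 1.36, CMBL by 0.78 and RPS27L by 0.57, and RPLP2 by -0.54 and SPRY4 by -0.45. TP53I11 (1.89) was lost without each library but the first non-induced p300/CBP one (adjusted p = 0.0543 to 0.21). ABCD2 (-0.65) was lost without each but the third induced p300/CBP, the second induced PCAF/GCN5 and the first non-induced PCAF/GCN5 ones (adjusted p = 0.061 to 0.195). SCD (-0.49) was lost without the first or second induced p300/CBP or the second non-induced PCAF/GCN5 library (adjusted p = 0.0625, 0.0677 and 0.0571), and SOX9 (-0.47) without the first induced p300/CBP or non-induced PCAF/GCN5 library 2 or 3 (adjusted p = 0.0629, 0.0556 and 0.0506).

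Further lists passed in that test between compounds. Sterol synthesis had a median of -0.117 (2 of 26 adjusted over the list alone, adjusted p = 0.000255) and immediate early genes one of -0.119 (3 of 25 adjusted over the list alone, adjusted p = 0.000795). Mitotic genes were at -0.128 (0 of 36 adjusted over the list alone, adjusted p = 3.94e-05, and adjusted p = 0.468 with an estimated correlation), TGF-beta and matrix genes at -0.16 (5 of 24, adjusted p = 9.01e-05, and adjusted p = 0.178 with an estimated correlation) and histone genes at -0.203 (1 of 14, adjusted p = 0.00585, and adjusted p = 0.153 with an estimated correlation). MYC targets were at 0.156 (3 of 30 adjusted over the list alone, adjusted p = 1.55e-09, and adjusted p = 0.153 with an estimated correlation) and ATF4 targets at 0.101 (2 of 26, adjusted p = 0.00346, and adjusted p = 0.153 with an estimated correlation). S phase genes had 0.112 (1 of 31 adjusted over the list alone, adjusted p = 0.000149, and adjusted p = 0.468 with an estimated correlation), but not without the third non-induced p300/CBP library (adjusted p = 0.108). Heat shock genes had 0.0886 (0 of 17 adjusted over the list alone, adjusted p = 0.0117, and adjusted p = 0.343 with an estimated correlation), but not without the first induced p300/CBP or the third induced PCAF/GCN5 library (adjusted p = 0.0718 and 0.0722).

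Splits of the samples were counted for each comparison. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and in each of the 7 comparisons of 2 groups 1 split, the real one, gave as many genes. The real counts and the highest of the other splits were 1478 and 2 for the p300/CBP compound without induction, 3 and 1 for the PCAF/GCN5 compound, 898 and 0, and 52 and 0, for the same in induced cells, 165 and 2, and 617 and 0, between the compounds without and with induction, and 2075 and 0 for induction. For the interactions 100 splits were drawn. As many genes were given by 7 of them for the p300/CBP compound (200 genes, highest other 932), by 13 for the PCAF/GCN5 compound (11 genes, highest other 30), and by 3 for the difference between compounds (51 genes, highest other 123). The highest other split of the first called several times the real count, which points to a structure of the samples: every split as large was among the 13 that left the induced libraries in their real groups, so it still carried the response of induced cells. The 87 splits that mixed these libraries called at most 0, 0 and 1 genes. The shares of the 100 (7%, 13% and 3%) thus rest on how many splits kept the induced groups, and they do not decide chance for any of the 3 interactions.

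The third induced DMSO library stood apart from its partners, with a score of 59.1 on the next largest axis of variance. Its depth of 23.6 M counts lay within that of the other induced libraries, and its p53 target level was nearer to its partners than to any other group by 0.465, where replicates had an SD of 0.0182, which argues against a wrong group. Its deviation followed GC content across genes (Spearman 0.322), but with the GC trend taken out of every library it was still 1.39 times the highest of the other 17, so GC content was not the whole cause. GC content as part of the cause, and gene length (-0.125), cannot be told apart from other causes: 2 other libraries had a larger GC trend (-0.411 and 0.337), which was to exclude it but does not, since several libraries carry such trends. A lower mitochondrial share (0.714%) may reflect a difference in the culture or in handling, which the design does not test.

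Genes of S phase and mitosis were lower with the p300/CBP compound where no p53 was induced. Action of residual tagged p53 on its targets would need a p53 target median of 0.416, if both medians kept their ratio on induction. The observed 0.0797 (bootstrap interval 0.0306 to 0.14) lay below it. That interval resamples the genes of the list, so it does not measure the spread between samples. A smaller residual action is not excluded. Without the third DMSO library, the shallow one, the S phase median was -0.63, and against the PCAF/GCN5 cultures in place of DMSO it was -0.479, which argues against a single shallow library or an unusual growth state of the DMSO cultures. An effect of the compound that needs no tagged p53 is a candidate explanation, which no test here addressed directly. The growth state of the 3 p300/CBP cultures themselves stays open.

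Neighbouring genes on chromosomes 1 and 20 rose together on induction. Of the 12 raised genes between RASAL2 and TOR3A and between NOP56 and GNRH2, 7 overlapped no other raised gene, which argues against reads shared between overlapping genes, and so did 12 of the 17 raised genes of the fullest 1 Mb windows there. Among all raised genes, 7.13% of random gene orders held a window as full as the fullest (9 genes, on chromosome 20 and, among 46 tested, on chromosome 11), so clusters by chance stay open for them, but for genes raised by 1 or more, 0 of 10000 orders reached the 7 of the chromosome 1 window (RASAL2-AS1 and the genes given in the report without FAM20B; 0.01% is the smallest share they can give, highest 6) and 0.76% the 5 of chromosome 20 (those given without PTPRA, and SLC4A11). With the p300/CBP compound in induced cells the 12 genes had a median of 0.0601 and the 17 one of 0.0871. The p53 targets raised on induction had 0.667 (bootstrap interval over genes 0.419 to 0.856). Of 905 genes raised on induction 155 were also called as raised by the compound, which does not measure the size of the response. The response of all raised genes as a set was not computed. A local effect stays possible, but the comparison with p53 targets alone cannot mark it out. A candidate explanation for the joint rise is that the inducible construct lies near the neighbouring genes and drives them. Insertion sites are not in the labels and were not tested.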

How the results depend on the processing

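The setting that leaves out the 4 libraries in doubt (the third of both DMSO groups, the second induced and the first non-induced PCAF/GCN5 library) was chosen after seeing the data; the other settings were set before. For counts that moved by over 1.5 times the cause was not tested, except where fewer or more genes or libraries enter by construction. Of 270 list tests 88 passed, and 35 did with an estimated correlation and 137 with fry in either direction (fry 61, replicate block 88, single libraries left out 81 to 98, with tests of comparisons without that library taken as they were). Of the 162 tests rerun with the libraries in doubt left out, 49 passed before and 57 after, which is 96 with the other tests as they were. Among lists that passed, the direction turned for mitochondrially encoded transcripts. Between compounds without induction theirs turned without the first PCAF/GCN5 library (adjusted p = 0.496, range 2.99e-08 to 0.496 over single libraries left out), and in the p300/CBP interaction without the third induced DMSO library (adjusted p = 0.74, range 1.14e-05 to 0.74) and with the libraries in doubt left out (0.505). Lists that had not passed turned and then passed in these cases: mitochondrially encoded transcripts with the PCAF/GCN5 compound without induction, upward without its first library (3.29e-27, range to 0.94) and without those in doubt (4.48e-33), and, without those in doubt, in the PCAF/GCN5 interaction, downward (1.09e-06, range 0.000307 to 0.595), and mitotic genes there (0.0224, range 0.0588 to 0.912). Over single libraries left out, 1983 list results stayed on their side of the threshold, 55 were lost, 65 gained and 3 turned, as given above.

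DESeq2 called 6 genes for the PCAF/GCN5 compound without induction, 1350 and 128 for the p300/CBP and PCAF/GCN5 compounds in induced cells, 443 between compounds without induction, 51 in the PCAF/GCN5 interaction and 108 in that between compounds, and 114 shared by both compounds in induced cells. With RLE scaling each of these counts stayed within 1.5 times. With no filter on low counts, where more genes are tested, the counts were 48 and 541 for the PCAF/GCN5 compound without and with induction, 2106 for the p300/CBP compound in induced cells, 594 between compounds without induction, and 416, 258 and 181 in the p300/CBP, PCAF/GCN5 and compound interactions. Shared calls were then 33 and 446 for both compounds without and with induction, 703 for the p300/CBP and 4 for the PCAF/GCN5 compound in both states. With a mean of at least 1 CPM the PCAF/GCN5 count without induction was 2 and both compounds shared 0 calls there.

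With all 6 groups in 1 fit the counts were 615 and 0 for the p300/CBP and PCAF/GCN5 compounds without induction, 2214 and 352 in induced cells, 394 between compounds in induced cells, 3455 for induction and 38 in the PCAF/GCN5 interaction, and both compounds shared 0 calls without and 295 with induction. The replicate block gave 14 for the PCAF/GCN5 compound and 46 between compounds without induction, 530 for the p300/CBP compound in induced cells, and shared calls of 6 for both compounds without induction and 222 for the p300/CBP compound in both states, though replicate numbers did not pair the samples. With the libraries in doubt left out the counts were 18 and 225 for the PCAF/GCN5 compound without and with induction, 4691 for induction, and 362 and 54 in the p300/CBP and PCAF/GCN5 interactions, and shared calls were 6 and 157 for both compounds without and with induction and 1 for the PCAF/GCN5 compound in both states. For the PCAF/GCN5 compound in induced cells rises and falls were 51 and 1, but 192 and 349 with no filter, 228 and 124 with all 6 groups and 191 and 34 without the libraries in doubt. The larger direction also turned for induction with all 6 groups (1780 rises and 1675 falls), for the PCAF/GCN5 interaction with no filter (72 and 186), for the PCAF/GCN5 compound without induction without the libraries in doubt (12 and 6) or its first library (9 and 8), for the p300/CBP compound in induced cells with the replicate block (288 and 242) or without 5 of its 6 libraries, the third DMSO one excepted, and between compounds in induced cells without the first PCAF/GCN5 library (287 and 256). The authors' tables listed 11 and 1223 for the PCAF/GCN5 compound and 2748 for the p300/CBP compound in induced cells.

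With each library left out in turn the counts ran from 527 to 2384 and 0 to 17 for the p300/CBP and PCAF/GCN5 compounds without induction, 263 to 3234 and 29 to 114 in induced cells, 1 to 310 and 236 to 1098 between compounds without and with induction, 869 to 5001 for induction, and 123 to 432, 8 to 24 and 34 to 58 in the p300/CBP, PCAF/GCN5 and compound interactions. Shared calls ran from 0 to 6 and 27 to 107 for both compounds without and with induction, and 88 to 902 for the p300/CBP compound in both states. Of 315 calls of named genes, 209 held in every setting, 106 were lost in at least 1 and 0 turned. By comparison, 53 of 59 held for induction, 32 of 46 and 15 of 21 for the p300/CBP and PCAF/GCN5 compounds in induced cells, 32 of 38 between them, 35 of 66 and 0 of 2 without induction, and 0 of 24 between them.

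Depth limits what the third non-induced DMSO library can show: with 9.1 M counts, 3 counts in it are 0.331 CPM, against 0.103 CPM in the deepest library.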

Other observations

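The test in this part was set before the result was seen. Among p53 targets in induced cells the response to the p300/CBP compound was uneven: CDKN1A rose by 2.75 and TP53I3 by 3.0, while MDM2 rose by 0.29. One hypothesis was that targets already raised most by induction rise least with the compound. Across 69 targets, which are not independent replicates, the Spearman correlation between the rise on induction and the response to the compound was 0.43, above the -0.715 to -0.185 that 20 simulations of unchanged groups with the same shared DMSO libraries gave. Across the 69 the hypothesis was not borne out, and targets raised more on induction tended to rise more with the compound. The 69 also hold targets that did not rise on induction, and such genes can raise the correlation if they respond to neither. Whether the hypothesis holds among the 48 that rose was not tested.

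The agreement of both compounds in induced cells exceeded that of simulated groups with shared controls, with a covariance of 0.0807 beside 0.0215. For the p300/CBP compound in both states, which share no libraries, the covariance was 0.0283 beside -0.000102. For the PCAF/GCN5 compound it was 0.00308 beside 3.11e-05.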
